A study of Mus musculus with 8 samples.

How the data were processed

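The study measured RNA in single cells of subcutaneous mouse tumors. MB49, a mouse urothelial cancer line, was injected under the skin of C57BL/6 mice that carry a tamoxifen-inducible Cre recombinase active in all tissues. In 4 libraries the host had 2 intact copies of Atg7, the gene of an enzyme needed to build autophagosomes. In the other 4 libraries the host carried floxed Atg7 copies that tamoxifen removes. Per the labels' protocols, tamoxifen was given on 4 days, tumor cells were injected 1 week later at 2 tumors per mouse, and tumors were collected 3 weeks after injection. Tumors were dissociated, filtered and spun through a density gradient before droplet encapsulation with a 10x Genomics 5' kit, and these steps can change the shares of cell types. The labels do not tie tumors to mice. Tumors of 1 animal may therefore be among the libraries, and p-values may then be too small. Libraries are named by host genotype and by the number that the labels give them: wild-type 1, 2, 5 and 6, and deleted 3, 4, 7 and 8.

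The deposited matrices hold natural log values, ln(1 + 10000 x UMIs of the gene / UMIs of the cell), with genes by symbol and cells by barcode. This unit was read from the values, because exp(value) - 1 sums to 10000 in every cell. The submitters' processing notes name Cell Ranger 2.1, Seurat 3.0 and the mm10 build; other steps are not given in the sources used here. The deposited cells had at least 498 UMIs, 201 to 5000 genes and under 20% mitochondrial UMIs, so cells outside these ranges were not analysed here. Each value was a whole multiple of its cell's smallest step within a tolerance of 0.01 UMI, for 100% of values, and whole UMIs were recovered from it. The 8 matrices held 29496 cells and 19024 gene symbols, of which 98.7% matched the GENCODE M21 annotation of mm10, the source of all coordinates.

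Total UMIs per library ran from 4371773 in deleted library 7 to 59235799 in wild-type library 6. Over all kept cells, the median UMIs per cell, averaged over libraries, was 7260 ± 1653 (SD, n = 4) in wild-type hosts and 2938 ± 1072 (SD, n = 4) in deleted hosts (exact permutation p = 0.0286). Shares of cells and classes with few cells have the lowest precision. Classes were compared only in libraries with at least 20 cells of the class, and wild-type library 1, with 17 dendritic-like and 6 NK-like cells, was left out for these 2 classes.

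Cells with under 200 genes or over 10% mitochondrial UMIs were removed (919 cells). Doublets were called with scrublet in scanpy 1.11.5 at an expected rate of 5%, and 104 more cells were removed. The caller marked 0.386% of the deposited cells, too few to count as a working doublet filter, so doublets remain among the 28473 kept cells. Of these, 1196 cells (4.20%) had over 4500 genes, close to the upper limit of the deposited cells. Cells were clustered on 2000 variable genes, 30 principal components and 15 neighbors with the Leiden method of igraph 0.11.9 at resolution 1, with seed 1. A cluster took a class name, used here as "X-like", from marker lists fixed beforehand, when at least 3 markers were detected in at least 10% of its cells. Clusters 21 and 23, with 244 cells (0.857%), stayed unnamed. No class contained a cluster whose leading 10 genes held more markers of another class.

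Shares of classes were compared between genotypes by a two-sided exact permutation test over libraries, with Benjamini-Hochberg adjustment over the classes. With 4 against 4 libraries the smallest p is 0.0286, and adjusted values over 9 classes cannot fall below the threshold unless many classes pass. T-like cells with a UMI of Cd8a or Cd8b1, of Cd4 or of Foxp3 were counted after thinning every cell to 1000 UMIs and leaving out shallower cells, and values without thinning are given too.

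Because the deposited values are logarithms, the test planned for count data was replaced by the fallback fixed beforehand for other units. For each gene, the mean deposited value over the cells of a class in a library, divided by ln 2, was compared between genotypes with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance and Benjamini-Hochberg adjustment. Log2 differences below are differences of these means, deleted minus wild type. They are smaller than the log2 of a fold for low genes, and the mean of logarithms depends on the depth of each cell, so a depth gap between genotypes can move them. Levels are given as UMIs per 10000, averaged over cells and then over libraries. A gene was tested where at least 5% of the class's cells had a UMI in at least as many libraries as the smaller group holds. Genes of 32 fixed lists were tested as sets with camera at a preset correlation of 0.01. This was repeated with an estimated correlation, with which no list passed in any class, and with fry. On simulated data with 200 changed genes, the T-like test recovered 2.00% of 2-fold and 28.3% of 4-fold changes in 7036 genes. In the monocyte/macrophage-like test, with 5845 genes, it recovered 2.00% and 39.0%. No unchanged gene was called in either. With a term for the barcode set, 74.7% and 89.0% of 4-fold changes were recovered, and 2.50% of the calls in the macrophage-like simulation were unchanged genes. The simulation drew the cells of each library from a single profile, with gene deviations independent of each other. It added a set effect of the form that the term fits, so the gain from the term was built in. Recovery and false calls need not be the same in the real classes.

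Cell barcodes showed that the libraries fall into 2 sets. The first 6 bases of barcodes were shared at 92.6% to 97.7% among libraries 1 to 4, at 100% among libraries 5 to 8, and at 23.4% to 26.3% between the sets. Each set holds 2 libraries of each genotype, and results within sets or with a set term stand beside the pooled ones.

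Named genes follow a rule fixed before the data were examined. It takes 12 genes always looked at, among them Atg7, Tmem173, Ifng, Cd8a, Foxp3, Gzmb, Cxcl9, Cd274, Arg1, Nos2 and Sqstm1, and 1 that is not reported here. It adds up to 10 genes each way with the largest change among genes at adjusted p under 0.05 without overlap between genotypes, and up to 4 passing members per list. Where fewer than 10 genes passed, the 10 with the lowest p were added. Variable receptor segments, of which none passed, and Xist and Y-linked genes, of which 4 passed over all cells and none within a class, were left out of the named genes. Other choices of filter, scale, doublet handling, clustering and library set were tried, and their effect is given in the closing section.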

Results

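Single-cell RNA was profiled in 8 MB49 tumors, 4 grown in Atg7 wild-type hosts and 4 in hosts whose Atg7 had been deleted before injection. The tumor cells themselves were not derived from the hosts. The series title asks whether host autophagy helps tumors with many mutations to grow by holding back a T cell response. The comparisons below therefore ask which cell types, T cell subsets and genes differed between tumors of the 2 host genotypes. The libraries held from 4371773 UMIs (deleted library 7) to 59235799 UMIs (wild-type library 6). After filtering, 28473 cells remained, from 941 in deleted library 7 to 5796 in wild-type library 5.

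Atg7 (ENSMUSG00000030314, mm10 chromosome 6, 114643097 to 114860614) was scarce in every library. Over all cells it stood at 0.411, 0.312, 0.145 and 0.160 UMIs per 10000 in wild-type libraries 1, 2, 5 and 6, and at 0.104, 0.166, 0.085 and 0.305 in deleted libraries 3, 4, 7 and 8. The genotypes overlapped (0.257 ± 0.127 against 0.165 ± 0.0995 SD, n = 4 each, exact permutation p = 0.257). In monocyte/macrophage-like cells of the host, 0.283 ± 0.133 compared with 0.0978 ± 0.0605 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.229 over 8 cell groups). The other host classes overlapped. The mean was higher in deleted hosts in neutrophil-like cells (0.430 ± 0.183 and 0.551 ± 0.209, SD, n = 4 each, exact permutation p = 0.429) and close in T-like cells (0.159 ± 0.0785 and 0.163 ± 0.0437, exact permutation p = 0.914). It was lower in fibroblast-like (0.156 and 0.101), dendritic-like (0.152 and 0.0432) and NK-like cells (0.197 and 0.0631), with exact permutation p = 0.629, 0.114 and 0.0857. Malignant-like cells, which came from the injected line, held 0.237 ± 0.122 and 0.251 ± 0.155 (SD, n = 4 each, exact permutation p = 0.886). The labels do not say which part of the gene is removed, and 5' UMIs from outside that part would remain, so this level is a weak check of the genotype. No library was set aside for it.

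Malignant-like cells made up a smaller share of every tumor of a deleted host than of any tumor of a wild-type host, and fibroblast-like and dendritic-like cells a larger share, although none of the 3 passed after adjustment. Malignant urothelial-like cells, which express epithelial keratins such as Krt8 and Krt18, made up 58.1% ± 10.95 (SD, n = 4) of cells in wild-type hosts and 5.22% ± 4.73 (SD, n = 4) in deleted hosts. Fibroblast-like cells, which produce collagens such as Col1a1 and Col3a1, made up 1.36% ± 0.620 and 17.9% ± 15.5 (SD, n = 4 each). Dendritic-like cells, led by Ccr7 and Ccl22, genes of migratory dendritic cells, made up 1.66% ± 0.614 and 3.87% ± 1.43 (SD, n = 4 each). In each of these classes all 4 deleted libraries lay on 1 side of all 4 wild-type libraries, which gave the smallest possible exact permutation p = 0.0286. Adjusted over 9 classes, p was 0.0857 for each, and permutation within the barcode sets gave its smallest value, p = 0.0556. The difference in malignant-like cells was -47.5 percentage points among libraries 1 to 4 and -58.3 among libraries 5 to 8. For fibroblast-like cells it was 11.7 and 21.3, and for dendritic-like cells 2.11 and 2.31. Fibroblast-like cells made up 36.9% of deleted library 7, and without it their difference was 10.15 percentage points, from 16.5. Dissociation and density centrifugation preceded every library and can set such shares.

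The remaining classes overlapped between genotypes over the 8 libraries. Monocyte/macrophage-like cells made up 23.7% ± 10.5 and 46.7% ± 18.5 (SD, n = 4 each, exact permutation p = 0.0857). Within each barcode set both deleted libraries lay above both wild-type libraries, with 56.4% and 64.9% against 33.6% and 30.05% among libraries 1 to 4 and 22.3% and 43.35% against 10.1% and 21.1% among libraries 5 to 8, and permutation within sets gave its smallest value (exact permutation p = 0.0556). NK-like cells made up 1.70% ± 1.02 and 4.45% ± 2.30 (exact permutation p = 0.114), and the difference of 2.745 percentage points turned to -0.313 at clustering resolution 0.5. T-like cells made up 7.18% ± 3.69 and 8.64% ± 3.18 (exact permutation p = 0.571), and the difference of 1.47 percentage points turned to -0.0889 without wild-type library 1 and was 4.48 at clustering resolution 0.5 (exact permutation p = 0.0286, adjusted p = 0.0643). Neutrophil-like cells made up 5.80% ± 2.08 and 10.7% ± 11.95 (exact permutation p = 0.743), and their difference of 4.94 percentage points turned to -0.994 without deleted library 8. Endothelial-like cells (0.190% ± 0.152 and 0.688% ± 0.790, exact permutation p = 0.400) and skeletal muscle-like cells (0.00908% ± 0.0182 and 0.330% ± 0.608, exact permutation p = 0.429) were rare. All immune classes together made up 40.1% ± 10.9 and 74.4% ± 17.9 (SD, n = 4 each, exact permutation p = 0.0571). Within the barcode sets they did not overlap, with 40.2% and 53.4% against 70.1% and 87.9% among libraries 1 to 4 and 26.85% and 39.8% against 50.9% and 88.9% among libraries 5 to 8 (exact permutation within sets, p = 0.0556, the smallest possible). As shares of immune cells, none of the 5 classes passed (adjusted p = 0.914 for each, exact permutation). T-like cells were 18.2% ± 8.05 of immune cells in wild-type hosts and 12.6% ± 7.39 in deleted hosts, monocyte/macrophage-like cells 57.7% ± 19.0 and 61.7% ± 18.1, neutrophil-like cells 15.1% ± 5.91 and 13.3% ± 12.7, dendritic-like cells 4.35% ± 1.87 and 5.88% ± 3.78, and NK-like cells 4.77% ± 3.89 and 6.60% ± 5.03 (SD, n = 4 each). The direction of these differences was not stable. At clustering resolution 0.5 the T-like difference of -5.62 percentage points became 5.19 and the NK-like difference of 1.83 became -9.03. With at least 500 genes per cell the NK-like difference was -0.893 and the neutrophil-like 4.45, from -1.80. Directions also turned for monocyte/macrophage-like cells without library 3 or 5 (-2.19 and -2.57, from 4.06), for neutrophil-like cells without library 3, 4 or 5 (0.898, 0.0945 and 0.512), and for dendritic-like (-0.195, from 1.53) and NK-like cells (-0.565) without library 7.

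**Figure D1:**
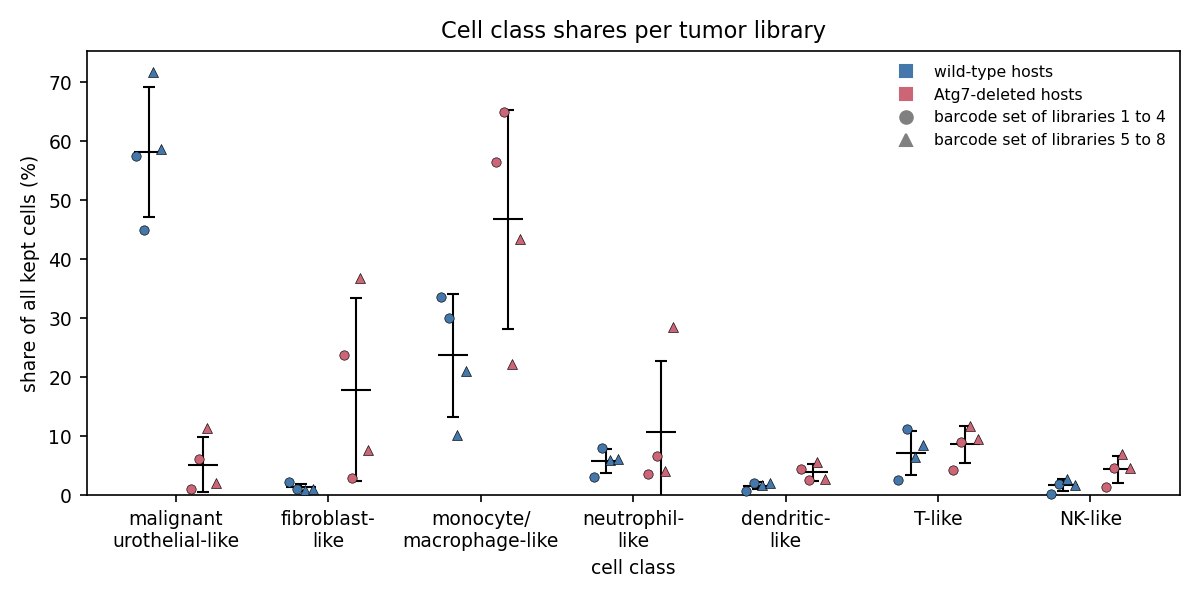
Share of all kept cells (%) in each cell class, with 1 point per tumor library, blue for wild-type and red for Atg7-deleted hosts, circles for libraries 1 to 4 and triangles for libraries 5 to 8, and black lines for the mean ± SD (n = 4; the axis ends at 0, below which 1 neutrophil-like bar would reach). Malignant urothelial-like cells averaged 58.1% and 5.22% with no overlap, while T-like cells averaged 7.18% and 8.64%.

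Within the T-like class, CD8 cells were fewer and CD4 cells more frequent in deleted hosts. Cells with a UMI of Cd8a or Cd8b1, which encode the coreceptor of cytotoxic T cells, made up 55.4% ± 7.13 of T-like cells in wild-type hosts and 17.8% ± 5.36 in deleted hosts at 1000 UMIs per cell (SD, n = 4 each). Cells with a UMI of Cd4, the coreceptor of helper and regulatory T cells, made up 5.59% ± 1.57 and 22.3% ± 5.68. Cells with a UMI of Foxp3, the transcription factor of regulatory T cells, made up 1.66% ± 0.694 and 4.66% ± 1.08. Each of the 3 shares separated the genotypes in all 8 libraries (exact permutation p = 0.0286, adjusted p = 0.0286). Permutation within barcode sets gave its smallest value for each (p = 0.0556), and the differences were alike in the sets, at -36.0 and -39.0 percentage points for Cd8a or Cd8b1, 16.4 and 17.1 for Cd4, and 2.61 and 3.40 for Foxp3. Without wild-type library 1, 2, 5 or 6 the exact permutation p of the Foxp3 share was 0.0571, at differences of 3.07, 3.16, 2.66 and 3.13 percentage points. Without thinning the shares were 72.1% ± 6.05 and 27.8% ± 10.0, 10.2% ± 2.39 and 40.7% ± 6.85, and 3.50% ± 0.631 and 8.42% ± 0.911 (SD, n = 4 each). The median depth of T-like cells was close between genotypes, at 3143 ± 1042 and 3167 ± 1219 UMIs (SD, n = 4 each, exact permutation p = 1). In malignant-like cells, which should lack these genes, the thinned shares averaged 0.0478%, 0.391% and 0.00956%, at median depths of 14136 ± 3121 UMIs in wild-type and 5930 ± 6237 UMIs in deleted hosts. In neutrophil-like cells they were 0.554%, 0.0149% and 0%.

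The cluster with the largest share of T-like cells differed between the genotypes. In wild-type hosts it was a cluster led by Cd8b1, Cd8a, Nkg7 and Gzmb, with 62.8% ± 6.75 of the class (21.2% ± 4.96 in deleted hosts). In deleted hosts it was a cluster led by Cd4, Tnfrsf4, Tnfsf11 and Cd40lg, genes of activated helper T cells, with 43.4% ± 11.5 (8.49% ± 1.46 in wild-type hosts, SD, n = 4 each). As a share of all cells, T-like cells with a Cd4 UMI rose from 0.709% ± 0.413 to 3.38% ± 1.01 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0457 over 8 measures). The 8 measures include the sizes of the 5 T-like clusters. For those led by Cd8b1, Cd4, Trdc and Foxp3, exact permutation p was 0.0286 each (adjusted p = 0.0457). Clusters led by Trdc and Foxp3 held 6.90% ± 1.47 and 4.08% ± 1.59 in wild-type and 13.5% ± 1.79 and 10.1% ± 1.84 in deleted hosts. The cluster led by Cd8a and Rgs16 held 17.8% ± 3.28 and 11.8% ± 7.66 (exact permutation p = 0.229). Leading genes of each cluster differed between genotypes in T-like cells, for the cluster led by Foxp3 only with a barcode set term. Cluster sizes and levels of these genes therefore cannot be told apart. T-like cells with a Cd8a or Cd8b1 UMI made up 5.09% ± 2.59 and 2.29% ± 0.975 of all cells and overlapped (exact permutation p = 0.114). T-like cells with a Foxp3 UMI made up 0.257% ± 0.165 and 0.720% ± 0.273 of all cells (exact permutation p = 0.0571).

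**Figure D2:**
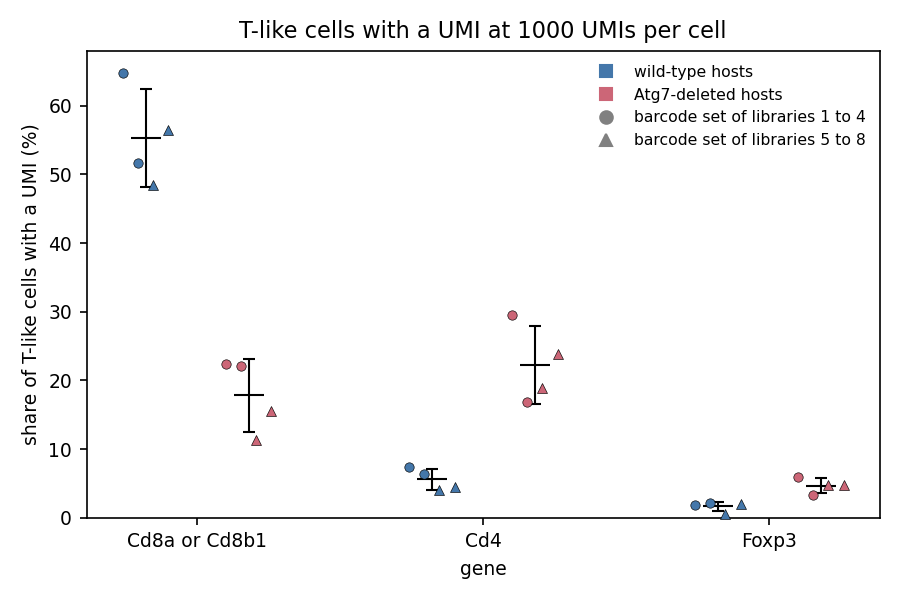
Share of T-like cells (%) with a UMI of Cd8a or Cd8b1, Cd4 or Foxp3 after thinning to 1000 UMIs per cell, with 1 point per tumor library, blue for wild-type and red for Atg7-deleted hosts, circles for libraries 1 to 4 and triangles for libraries 5 to 8, and black lines for the mean ± SD (n = 4). The genotypes do not overlap for any of the 3, with Cd8a or Cd8b1 at 48.4% to 64.8% in wild-type and 11.3% to 22.4% in deleted hosts.

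Averaged over T-like cells, Cd8a, Cd8b1, Ccl5, Nkg7 and Prf1 fell and Cd4 rose in deleted hosts. Cd8a (chromosome 6, 71373427 to 71379173) fell from 5.16 ± 0.681 to 1.21 ± 0.602 UMIs per 10000 (SD, n = 4 each; log2 difference -1.30, SE 0.16, limma adjusted p = 0.00622), and Cd8b1 from 6.00 ± 1.93 to 1.78 ± 0.764 (log2 difference -1.27, adjusted p = 0.0304). Cd4 (chromosome 6, 124864692 to 124888221) rose from 0.716 ± 0.128 to 3.37 ± 0.984 (log2 difference 0.92, SE 0.12, adjusted p = 0.00622). Ccl5, a chemokine of activated T cells (chromosome 11, 83525778 to 83530518), fell 3.95-fold from 75.1 ± 23.8 to 19.0 ± 6.02 (adjusted p = 0.0169). Nkg7, a protein of cytotoxic granules, fell 3.41-fold from 20.3 ± 7.69 to 5.97 ± 0.707 (adjusted p = 0.0388). Prf1, the pore-forming perforin, fell 4.52-fold from 3.38 ± 1.80 to 0.748 ± 0.656 (adjusted p = 0.0367). Gzmb, which encodes granzyme B, stood at 21.7 ± 10.6 and 8.15 ± 2.41 and passed only with a barcode set term (adjusted p = 0.0562 without it and 0.000859 with it). Foxp3 (0.349 ± 0.136 and 0.757 ± 0.310, adjusted p = 0.0986) and Ifng, the cytokine interferon gamma (1.79 ± 0.729 and 1.90 ± 0.787, adjusted p = 0.905), did not pass.

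Among the 40 genes that rose in T-like cells were Furin, Rora, Maf and Nr4a1. Levels of the genes named here are means over all T-like cells, whose mix of CD8 and CD4 cells differed between genotypes. They do not show a change within a cell type. Furin, a protease that matures precursor proteins, rose 3.33-fold from 1.73 ± 0.437 to 5.77 ± 0.961 UMIs per 10000 (SD, n = 4 each; log2 difference 1.06, SE 0.14, limma adjusted p = 0.0078). Rora, a nuclear receptor of interleukin 17-producing and innate lymphocytes, rose 2.56-fold, and Maf, a transcription factor of helper T cells, rose 3.70-fold (adjusted p = 0.0151 for both). Rora was also among the 10 leading genes of the T-like cluster led by Cd4 and of a smaller T-like cluster led by Trdc, Cd163l1, Il17a and Tcrg-C1, genes of gamma delta T cells that make interleukin 17. Nr4a1, an early target of T cell receptor signals, rose 3.29-fold (adjusted p = 0.0113). Emb rose 2.23-fold, Cish, a feedback inhibitor of cytokine and receptor signals, 2.19-fold, Zfp36l1, an RNA-binding protein that promotes mRNA decay, 2.92-fold, Dusp5, a phosphatase of ERK kinases, 2.45-fold, and Pim1, a kinase induced by cytokines, 2.41-fold. Adjusted p for these 5 lay between 0.0222 and 0.0321. Dut, which keeps uracil out of DNA, fell 2.13-fold, and Pclaf, a partner of the replication clamp, 2.29-fold. In the cluster led by Cd8b1 alone the log2 difference of Pclaf was 0.00412. Cx3cr1, a chemokine receptor, fell 4.49-fold. Wfdc2 and Krt18 fell too, at 5.30% and 5.46% of their level in the class where each was highest, a level that free RNA can give.

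Of 7043 genes tested in T-like cells, 40 were higher and 18 lower in deleted hosts, and 541 passed with a barcode set term. Without overlap between genotypes were 9.43% of tested genes, against 2.86% by chance. Summed UMIs with median-ratio scaling moved the balance to 72 higher and 94 lower. Of 16 tested genes of the cytotoxic effector list, 3 fell, none rose and 13 did not pass (6 fell when adjusted over the list alone). The list's median log2 difference was -0.26 (camera adjusted p = 2.14e-07, adjusted p = 0.371 with an estimated correlation). Of 22 cell cycle genes, 1 fell, Birc5, an inhibitor of apoptosis active in mitosis, and 21 did not pass (12 fell when adjusted over the list alone, adjusted p = 0.371 with an estimated correlation). Birc5 had a log2 difference of 0.0101 in the cluster led by Cd8b1 alone. Of 18 genes that respond to tissue dissociation within minutes, Nr4a1 and Fosb rose and 16 did not pass (7 rose when adjusted over the list alone, adjusted p = 0.501 with an estimated correlation). Of 10 genes of naive and memory T cells, Klf2, which keeps T cells in circulation, rose from 0.525 ± 0.138 to 1.89 ± 0.947 and 9 did not pass (5 rose and 1 fell when adjusted over the list alone, adjusted p = 0.371 with an estimated correlation). None of 12 tested regulatory T cell genes passed, and 3 rose when adjusted over the list alone. Of 15 NF-kB target genes, Nfkbiz rose 2.21-fold and Birc3 2.25-fold (3 rose when adjusted over the list alone). Of 20 interferon gamma response genes Igtp, a guanosine triphosphatase of defense against microbes, rose 2.38-fold and 19 did not pass (2 rose and 1 fell when adjusted over the list alone). Ifit3 was the 1 of 20 type I interferon response genes that fell (from 0.301 ± 0.0206 to 0.0850 ± 0.0537; 2 fell when adjusted over the list alone, adjusted p = 0.538 with an estimated correlation). The number of genes called fell to 4, 5, 9, 17, 12, 27, 23 and 27 when libraries 1 to 8 were left out in turn, and to 0 without the detection filter or at clustering resolution 0.5. Cd8a, Cd4 and Furin passed whichever library was left out. Ccl5 did not pass without library 1, 2, 3 or 7 (adjusted p = 0.0762, 0.0819, 0.0595 and 0.0534), Nr4a1 without library 1 or 2 (0.0568 and 0.0534), Rora without 1 or 2 (0.0762 and 0.0952), Maf without 1 or 5 (0.0762 and 0.0588), and the other called genes named here lost their calls without 2 to 8 of the libraries. In the cluster led by Cd8b1 alone, 1 gene passed.

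**Figure D3:**
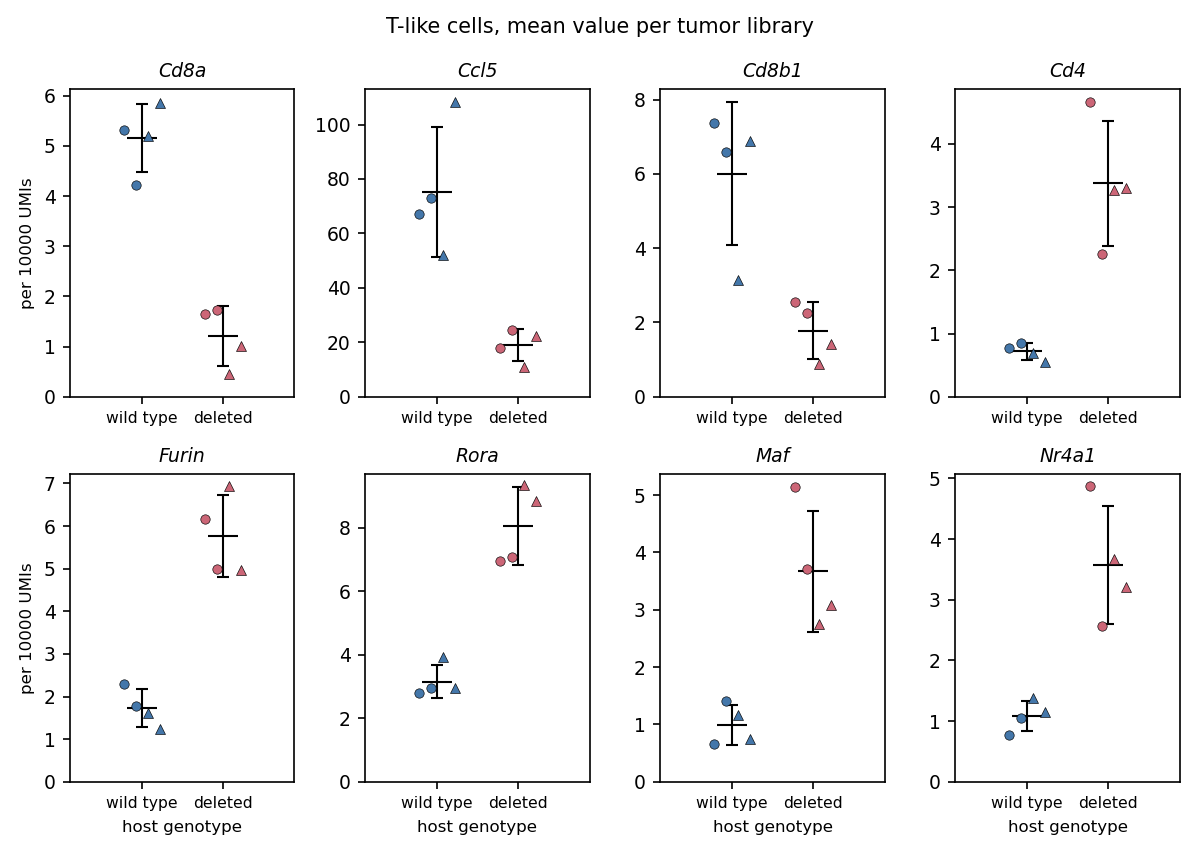
Mean UMIs per 10000 in T-like cells for 8 genes, with 1 point per tumor library, blue for wild-type and red for Atg7-deleted hosts, circles for libraries 1 to 4 and triangles for libraries 5 to 8, and black lines for the mean ± SD (n = 4). Cd8a, Ccl5 and Cd8b1 lay lower and Cd4, Furin, Rora, Maf and Nr4a1 higher in all 4 deleted libraries, with Cd8a at 5.16 and 1.21 on average.

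In NK-like cells of deleted hosts, transcripts of 2 receptor genes of the NK gene complex on chromosome 6 fell to or near 0. Klrb1b, an inhibitory lectin-like receptor (chromosome 6, 128813706 to 128826331), fell from 1.41 ± 0.502 to 0.0339 ± 0.0286 UMIs per 10000 (SD, n = 3 and 4; log2 difference -0.57, SE 0.07, limma adjusted p = 0.00563). Klra8, which encodes Ly49H, an activating receptor for a protein of mouse cytomegalovirus (chromosome 6, 130115226 to 130129898), fell from 0.816 ± 0.279 to 0 (adjusted p = 0.0353). It had 62 UMIs in 322 wild-type cells and 0 in 463 deleted cells over the group, which allows a share of cells with a UMI of up to 0.648%. Klra4 (0.947 ± 0.102 and 0.0427 ± 0.0419, adjusted p = 0.109) and Klra9 (0.724 ± 0.196 and 0.037 ± 0.0505, adjusted p = 0.156) passed only with a barcode set term (adjusted p = 0.00737 and 0.00708). Klra genes are near-identical paralogs whose UMIs the counting can assign to one another, and Klra4, Klra8 and Klra9 were among the markers that named the class. Other receptor genes of the complex, chosen after their values were seen, did not pass. Klra3 had 24 UMIs in wild-type and 155 in deleted hosts (log2 difference 0.24, adjusted p = 0.435), Klra7 138 and 222 (-0.07, adjusted p = 0.801), Klrd1 363 and 697 (0.14, adjusted p = 0.823), Klrb1c 134 and 126 (-0.27, adjusted p = 0.435) and Klre1 134 and 181 (-0.16, adjusted p = 0.563). The NK-like cells had a median of 1928 ± 543 UMIs in wild-type and 3876 ± 1352 UMIs in deleted hosts (SD, n = 3 and 4, exact permutation p = 0.0857).

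Among the other genes of NK-like cells with the lowest p, none passed. Azin1, which raises polyamine synthesis, Hsph1, a chaperone, Pbxip1, Ap2b1, a part of the clathrin adaptor, and Pianp had higher means and Ifitm1, an antiviral membrane protein, a lower mean in deleted hosts (adjusted p = 0.435 for each). Ifng (0.821 ± 0.313 and 1.78 ± 1.55, SD, n = 3 and 4) and Gzmb (12.2 ± 1.79 and 6.11 ± 2.13) did not pass, with limma adjusted p = 0.435 and 0.601. Of 19 cytotoxic effector genes none passed, adjusted over the list alone too, and the median log2 difference of 0.02 opposed the camera direction, which was down (adjusted p = 0.667 with an estimated correlation). Of 6780 genes, none was higher and 2 were lower. At unadjusted p under 0.05 there were 767, 5 passed with the set term, and 12.3% did not overlap between genotypes against 5.71% by chance. The 2 calls became 0 without deleted library 4 or 8 (adjusted p = 0.0564 and 0.0614 for Klrb1b, 0.221 and 0.241 for Klra8), 1 without wild-type library 6 or deleted library 7 (adjusted p = 0.135 and 0.183 for Klra8), 3 without deleted library 3 and 4 without wild-type library 5. They became 13 at clustering resolution 0.5 and 169 with the called doublets kept.

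**Figure D4:**
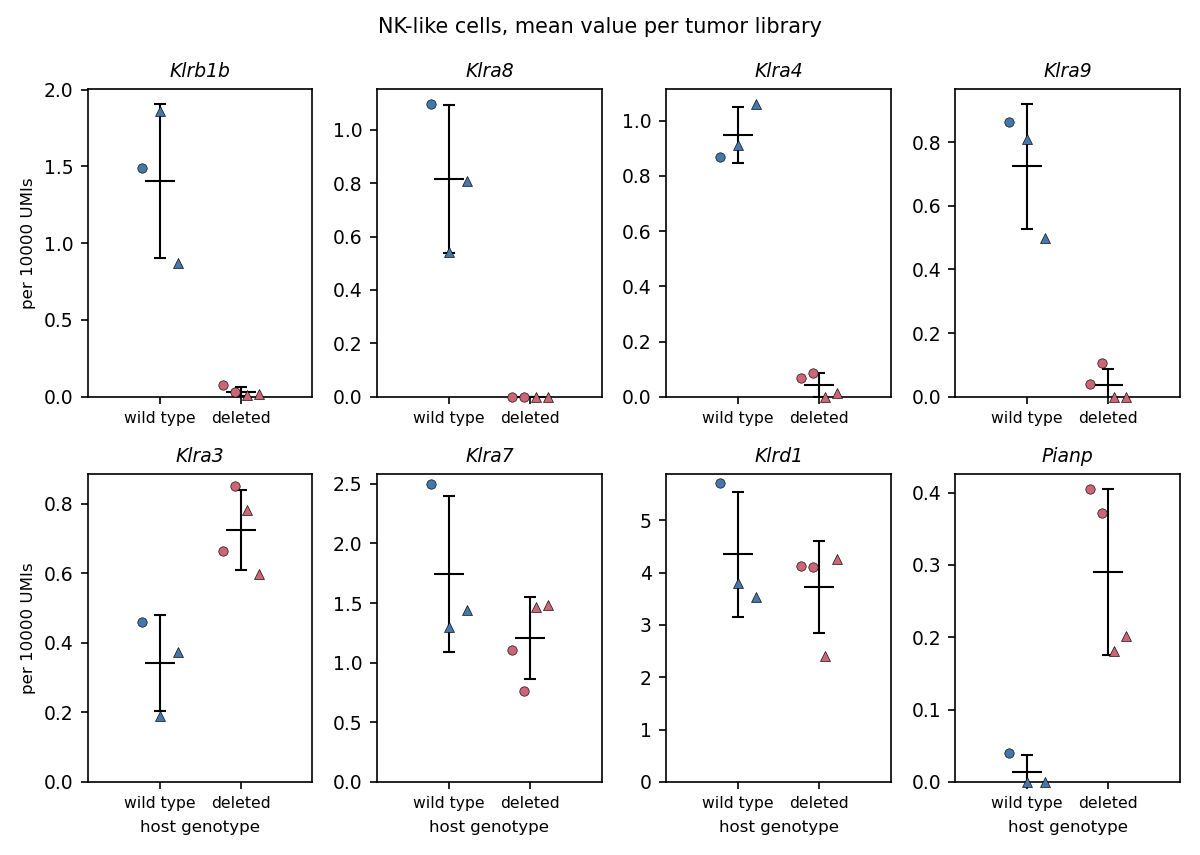
Mean UMIs per 10000 in NK-like cells for 7 NK receptor genes and Pianp, with 1 point per tumor library with at least 20 cells, blue for wild-type (n = 3) and red for Atg7-deleted hosts (n = 4), circles for libraries 1 to 4 and triangles for libraries 5 to 8, and black lines for the mean ± SD. Klrb1b (1.41 and 0.0339 on average) and Klra8 (0.816 and 0) lay lower in all 4 deleted libraries, whereas the means of Klra3, Klra7 and Klrd1 did not differ past the threshold.

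In the few malignant-like cells of deleted hosts, genes of the mitochondrial genome and of the cell cycle were among those that fell. Of 13 genes encoded in mitochondrial DNA, which specify respiratory chain subunits, 7 fell, none rose and 6 did not pass (10 fell when adjusted over the list alone). mt-Co2 (mitochondrial genome, 7013 to 7696) fell from 95.1 ± 10.7 to 42.0 ± 11.9 UMIs per 10000 (SD, n = 4 each; log2 difference -2.01, SE 0.32, limma adjusted p = 0.00697), mt-Nd1 from 31.9 ± 9.98 to 12.4 ± 4.55 (adjusted p = 0.0173) and mt-Co3 from 75.6 ± 40.1 to 28.7 ± 10.1 (adjusted p = 0.0197). The median depth of the class was 14136 ± 3121 and 5930 ± 6237 UMIs per cell, and mt-Co2 did not pass after thinning to 1000 UMIs, at a log2 difference of -2.05 (adjusted p = 0.0831, and from 0.000847 to 0.422 over the alternatives tried). The list's median log2 difference was -1.83 (camera adjusted p = 0.000549, and 2.48e-08 after thinning, with the direction down in both; adjusted p = 0.289 with an estimated correlation). Of 10 MHC class II presentation genes, 6 fell, among them H2-DMa and H2-DMb1, which load peptides, and the class II chains H2-Aa and H2-Eb1 (8 fell and 1 rose when adjusted over the list alone, adjusted p = 0.582 with an estimated correlation). H2-Aa stood at 6.05 ± 0.947 and 2.48 ± 1.60, at 4.85% of its level in the highest class, and Cd74, the invariant chain, which fell too, at 6.95%. Immune classes, in which these genes were highest, made up a mean of 40.1% of cells in wild-type and 74.4% in deleted hosts, and all 8 tested class II genes had higher means in monocyte/macrophage-like cells of deleted hosts. Of 26 cell cycle genes 8 fell, such as Cenpf, Ccnb1 and Ccnb2, which act in mitosis, and 18 did not pass (17 fell when adjusted over the list alone, adjusted p = 0.582 with an estimated correlation). The cell cycle list had camera adjusted p = 0.000244, and after thinning it did not pass (camera adjusted p = 0.102, direction down in both). Of 17 amino acid stress response genes 5 fell, among them Phgdh and Psat1, enzymes of serine synthesis (8 when adjusted over the list alone, camera adjusted p = 0.105, and 0.976 after thinning). Phgdh fell from 2.69 ± 0.709 to 1.42 ± 0.371 (adjusted p = 0.0263). Of 17 hypoxia genes 3 fell, Egln3, Bnip3l and Adm (7 when adjusted over the list alone). mt-Co2, H2-DMa, H2-DMb1, H2-Aa and Egln3 passed whichever library was left out. H2-Eb1 did not pass without deleted library 4 (adjusted p = 0.0546), and mt-Nd1 without library 2 or 4 (0.0641 and 0.0538). mt-Co3 and Cenpf did not pass without library 2, 4 or 8, Ccnb1 without 2, 6 or 8, Ccnb2 and Bnip3l without 2, 4, 6 or 8, Cd74 without 2, 3, 4, 6 or 7, Phgdh without 2, 3, 4, 6 or 8, Psat1 without 2, 4, 5, 6 or 8 and Adm without 1, 2, 4, 6 or 8 (adjusted p from 0.0502 to 0.0912).

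Cd274, Gbp5, Iigp1 and Cxcl16 rose in malignant-like cells, each at under 20% of its level in the class where it was highest, so that free RNA of other cells can contribute. Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29367455 to 29388095), rose 3.03-fold from 0.478 ± 0.166 to 1.45 ± 0.273 UMIs per 10000 (SD, n = 4 each; log2 difference 0.35, SE 0.08, limma adjusted p = 0.0173), at 3.79% of its level in the highest class, while all immune classes together made up 40.1% ± 10.9 and 74.4% ± 17.9 of cells. Gbp5 and Iigp1, guanosine triphosphatases of defense against microbes, rose 3.29-fold and 3.53-fold, and Cxcl16, a chemokine for activated T cells, rose 2.64-fold, at 17.2%, 17.9% and 16.3% of their level in the highest class. Of 22 interferon gamma response genes 3 rose, Ciita, the activator of class II genes, fell and 18 did not pass (4 rose and 1 fell when adjusted over the list alone; median log2 difference 0.16, adjusted p = 0.127 with an estimated correlation). Of 9 chemokine genes that attract T cells, Cxcl16 and Ccl5 rose (2 when adjusted over the list alone, adjusted p = 0.127 with an estimated correlation), with Ccl5 at 1.44% of its level in the highest class. AA467197 rose 3.87-fold from 3.19 ± 0.827 to 12.3 ± 3.96 and had its highest level in this class, and Lcn2, which binds bacterial iron carriers, rose 5.98-fold, at 19.2% of its level in the highest class. Abca1, a cholesterol exporter, Plac8 and Ifi206, an interferon-inducible gene, rose from levels under 0.0785 to 0.334 ± 0.145, 0.647 ± 0.369 and 0.338 ± 0.0700, with Abca1 and Plac8 at 3.57% and 3.46% of their level in the highest class. Cavin3, a coat protein of caveolae, fell 3.80-fold from 4.32 ± 1.25 to 1.14 ± 0.399 (adjusted p = 0.00476), S100a4, a calcium-binding protein of motile cells, from 12.7 ± 5.22 to 5.47 ± 2.28, and Krt18 from 11.8 ± 3.25 to 5.28 ± 1.92. The 82 ribosomal protein genes, none of which passed, had a median log2 difference of -0.40 and a camera direction of up, and the 2 differ in sign. Cavin3, Abca1 and Ifi206 passed whichever library was left out. Cd274 did not pass without wild-type library 2 or 6 (adjusted p = 0.0521 and 0.0595). Gbp5 did not pass without library 2, 6 or 8, Iigp1 without 2, 5 or 6, Lcn2 without 2, 5, 6 or 8, S100a4 without 1, 2, 4 or 8, Cxcl16 without 2, 4, 5, 6 or 8, Krt18 without 2, 3, 4, 6 or 8, AA467197 without 1 to 6, Plac8 without 1, 2, 4, 5, 6 or 8, Ciita without 1, 2, 4, 6, 7 or 8 and Ccl5 without any library but 7 (adjusted p from 0.05015 to 0.1045).

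In all, 14 genes were higher and 986 lower among 9322 tested in malignant-like cells, and 21.5% did not overlap between genotypes against 2.86% by chance. These counts depend on the scale and the depth of the cells. The log2 of the mean plus 1 gave 0 higher and 2 lower, summed UMIs as CPM 7 and 28, median-ratio scaling 19 and 31, and thinning to 1000 UMIs 0 and 1. The class came from 9943 cells of wild-type and 401 of deleted hosts. A cluster with a median of 1000 UMIs per cell held 4.65% ± 4.80 of it in wild-type and 26.2% ± 21.04 in deleted hosts (SD, n = 4 each). The largest clusters followed the barcode sets. A cluster led by Hist1h2ap, Ube2c, Birc5 and Cenpf held 35.05% and 27.25% of the class in wild-type libraries 5 and 6. It held 11.1% and 6.73% in deleted libraries 7 and 8, and 0% to 0.162% in libraries 1 to 4. A cluster led by Hspb1 and Gsta4 held 83.0% and 89.7% of the class in wild-type and 70% and 33.6% in deleted hosts among libraries 1 to 4, and 0.403% to 15.7% in libraries 5 to 8, where a cluster led by Ccdc85b and Mt3 held 26.2% to 58.3%, against 4.21% to 8.72% in libraries 1 to 4. Leaving out wild-type library 2 or 6 or deleted library 4 or 8 lowered the total of 1000 to 243, 347, 234 and 239. Cxcl9 (0.508 ± 0.0614 and 2.93 ± 3.31, adjusted p = 0.0993), Nos2, Sqstm1, an autophagy receptor, and Tmem173, which encodes STING, did not pass (adjusted p from 0.0993 to 0.699).

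In neutrophil-like cells of deleted hosts, Psap, Creg1, Ly6i and the class I genes H2-Q7 and H2-Q6 rose, and 3 genes fell. Psap, a precursor of lysosomal activators (chromosome 10, 60277627 to 60302597), rose 3.65-fold from 9.39 ± 3.56 to 34.2 ± 7.19 UMIs per 10000 (SD, n = 4 each; log2 difference 2.07, SE 0.39, limma adjusted p = 0.0374). The class I genes H2-Q7 and H2-Q6, near-identical paralogs whose UMIs are uncertain, rose 4.71-fold and 7.96-fold. Creg1, a lysosomal glycoprotein, rose 4.504-fold and Ly6i 5.07-fold. Of 20 lysosomal genes on the fixed list Psap rose and 19 did not pass (1 rose when adjusted over the list alone, camera adjusted p = 0.384). Lmnb1, a lamin of the nuclear envelope, fell 3.48-fold, Ifitm2, an antiviral membrane protein, 3.50-fold, and G0s2, an inhibitor of fat breakdown that was also a marker of the class, 3.05-fold. Of 18 class I presentation genes 2 rose and 16 did not pass (9 rose when adjusted over the list alone; median log2 difference 0.50, adjusted p = 0.406 with an estimated correlation). None of 15 interferon gamma response genes passed, though 8 rose when adjusted over the list alone (adjusted p = 0.549 with an estimated correlation). S100a9, a calcium-binding protein of neutrophil granulocytes, stood at 324 ± 72.3 and 169 ± 76.9 (adjusted p = 0.0693), Cd274 at 20.1 ± 3.31 and 30.7 ± 11.1 (adjusted p = 0.411). Of 2278 genes, 5 were higher and 3 lower, 190 passed with a barcode set term, and 12.3% did not overlap between genotypes against 2.86% by chance. The 8 calls became 0 without wild-type library 1, 2 or 5, 1 without wild-type library 6 or deleted library 4, 3 without deleted library 3, 16 without deleted library 7 and 30 without deleted library 8. They became 6 higher and 1 lower with summed UMIs as CPM, and 0 with median-ratio scaling.

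In fibroblast-like cells of deleted hosts, 3 genes rose and Acta2, a gene of contractile cells, fell. Acta2 encodes the smooth muscle actin of myofibroblasts (chromosome 19, 34241090 to 34255590) and fell from 6.12 ± 3.57 to 0.791 ± 0.701 UMIs per 10000 (SD, n = 4 each; log2 difference -0.996, SE 0.154, limma adjusted p = 0.00958). C1rb, a complement protease gene (chromosome 6, 124570294 to 124581171), had 0 UMIs in 198 wild-type cells over the group, which allows a share of cells with a UMI of up to 1.52%, and 1553 in 1702 deleted cells (0.895 ± 0.471 per 10000, adjusted p = 0.00221). Col6a6, a chain of collagen VI, had 0 and 473 UMIs in the same cells (0.353 ± 0.0765 per 10000, adjusted p = 0.00696). Pianp (chromosome 6, 124996694 to 125003096) rose 30.9-fold from 0.0321 ± 0.0269 to 0.992 ± 0.240 (adjusted p = 0.00581). In T-like cells Pianp, chosen after its values were seen, had 46 and 162 UMIs and rose too (adjusted p = 0.0388), and in dendritic-like cells 8 and 282 (adjusted p = 0.117). Tagln, a marker of contractile cells, and Col8a1 had lower means, and Saa3, an acute phase protein, Clec3b, Clip4 and Lpl, a lipase, higher means, but did not pass (adjusted p from 0.0622 to 0.0651). None of 19 genes of the matrix list passed (1 rose and 1 fell when adjusted over the list alone). Of 9316 genes, 3 were higher and 1 lower, 4 were higher and none lower on summed UMIs by either scaling, 100 passed with the set term, and 4.84% did not overlap against 2.86% by chance. The 4 calls became 11 without wild-type library 1 or deleted library 7 and 48 without deleted library 8. Acta2 lost its call without deleted library 3 (adjusted p = 0.126), and Col6a6 without wild-type library 2, 5 or 6 (adjusted p = 0.0876, 0.0608 and 0.0532).

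In dendritic-like cells of deleted hosts, Klrd1 fell and Ubash3b rose. Klrd1, the CD94 receptor chain (chromosome 6, 129591782 to 129598775), fell 6.17-fold from 1.96 ± 0.245 to 0.317 ± 0.0675 UMIs per 10000 (SD, n = 3 and 4; log2 difference -0.65, SE 0.09, limma adjusted p = 0.0103). Ubash3b, a phosphatase of kinase signalling, rose 4.07-fold from 0.342 ± 0.0583 to 1.39 ± 0.194 (adjusted p = 0.0354). Klrb1b, Ifitm1 and Ifitm3 had lower means and Aplp2, Shtn1, Tsc22d3 and Asap1 higher means and did not pass (adjusted p from 0.109 to 0.139). None of 26 type I interferon response genes passed, though 13 fell when adjusted over the list alone, with a median log2 difference of -0.25 (camera adjusted p = 3.22e-31, adjusted p = 0.0843 with an estimated correlation). All 8 tested cytotoxic effector genes, Klrd1 among them, had lower means, and 7 did not pass (2 fell when adjusted over the list alone; camera adjusted p = 5.35e-07, adjusted p = 0.202 with an estimated correlation). Of 7416 genes, 1 was higher and 1 lower, 888 had an unadjusted p under 0.05, 25 passed with the set term, and 11.8% did not overlap against 5.71% by chance. Both scalings of summed UMIs gave 1 lower gene and no higher one. The 2 calls became 0 without deleted library 3, 7 or 8 or wild-type library 6, 1 without wild-type library 2 and 5 without wild-type library 5. Klrd1 did not pass without library 3, 6, 7 or 8 (adjusted p = 0.0592, 0.0724, 0.0505 and 0.0718), and Ubash3b without library 2, 3, 5, 6, 7 or 8 (adjusted p from 0.0505 to 0.402).

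No gene passed in monocyte/macrophage-like cells. With limma, 223 of 5678 genes had an unadjusted p under 0.05, 97 passed with a barcode set term (87 of them higher), 2 passed on the log2 of the mean plus 1, and 0 passed on summed UMIs by either scaling. Without overlap were 3.08% of genes, against 2.86% by chance. Arg1, the arginase of suppressive macrophages, stood at 15.6 ± 4.15 and 29.9 ± 9.45 UMIs per 10000 (SD, n = 4 each), and Cxcl9, a chemokine induced by interferon gamma, at 2.97 ± 1.22 and 0.624 ± 0.393. Spic, a transcription factor of iron-recycling macrophages (0.861 ± 0.183 and 0.128 ± 0.0955), and Abca1 (2.60 ± 1.01 and 8.53 ± 2.46) were among those with the lowest p (adjusted p = 0.999 for each of these 4 genes, and 0.0637, 0.129, 0.0173 and 0.01 with the set term for Cxcl9, Arg1, Spic and Abca1). Of 8 MHC class II genes none passed, also when adjusted over the list alone (median log2 difference 0.65, adjusted p = 0.515 with an estimated correlation), and the same held for 25 type I interferon response genes (median -0.12, adjusted p = 0.515 with an estimated correlation). Clusters of this class differed between libraries: 3 of the 6 clusters took 88.4%, 95.2% and 93.1% of their cells from a single deleted library each, and the cluster led by Mmp13 and Inhba held 62.0% and 66.3% of the class in wild-type libraries 1 and 2 and 0.340% to 4.13% in the other 6 libraries, wild-type 5 and 6 among them.

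Over all cells together, the keratin genes Krt18 and Krt8 fell and the collagen genes Col3a1 and Col1a1 rose, alongside the difference in cell class shares. Krt18 fell 18.9-fold from 6.997 ± 1.497 to 0.371 ± 0.340 UMIs per 10000 (SD, n = 4 each; log2 difference -1.90, SE 0.14, limma adjusted p = 0.000152), and Krt8 10.6-fold. Phgdh fell 8.08-fold, and Ccnb1 and Plk1 were among 22 of 25 cell cycle genes that fell (23 when adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). Of 82 ribosomal protein genes 23 fell (23 when adjusted over the list alone, adjusted p = 0.684 with an estimated correlation), such as Rplp0 and Rpl32. Gapdh fell 3.74-fold with 8 other genes of 15 in glycolysis (10 fell and 1 rose when adjusted over the list alone, adjusted p = 0.577 with an estimated correlation). Col3a1 rose 18.4-fold from 1.84 ± 1.09 to 33.7 ± 27.1 and Col1a1 10.1-fold, and 6 of 15 matrix genes rose and 1 fell (7 and 1 when adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). Egr1, Dusp1 and Nr4a1, genes that respond to dissociation, were among 10 of 18 that rose (10 when adjusted over the list alone, adjusted p = 0.495 with an estimated correlation), Egr1 4.11-fold and Dusp1 3.38-fold. Pim1 rose 2.40-fold, Klf2 3.43-fold and Arg1 3.55-fold (adjusted p = 0.0377, and 0.0712, 0.0621, 0.104 and 0.0927 without libraries 2, 3, 5 and 6), while Spp1, which encodes osteopontin, fell 2.57-fold. Of 20 core autophagy genes only Ulk1, the kinase that starts autophagy, rose, and none passed when adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). Ulk1 did not pass without library 4, 5 or 6 (adjusted p = 0.0585, 0.0823 and 0.0947), nor Col3a1 without wild-type library 6 (0.0504). None of 7 neutrophil transcripts, 8 cytotoxic effector genes or 22 lysosomal genes passed, adjusted over the list alone too, and 5 of 22 class I presentation genes fell and none rose (2 fell when adjusted over the list alone; adjusted p = 0.495, 0.577, 0.545 and 0.952 with an estimated correlation for these 4 lists). Of 8760 genes 399 were higher and 2196 lower, and 32.4% did not overlap against 2.86% by chance. Summed UMIs gave 1429 higher and 1677 lower as CPM and 1316 and 2097 with median-ratio scaling.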

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

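Chosen only after the results were seen were the 3 tests on the share of CD8 cells, the bound for the depth of malignant-like cells, the reading of the chromosome 6 test and its counts of calls, the depth test of NK-like cells, and the gene counts after thinning and without the low-UMI cluster as settings; the other tests were fixed before their results were seen.

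In malignant-like cells, 986 genes were lower in deleted hosts, with a median log2 difference of -0.24, and the cells had a median of 5930 ± 6237 UMIs against 14136 ± 3121 in wild-type hosts (SD, n = 4 each). With every cell thinned to 1000 UMIs, 1 gene (0.101% of that number) was called lower, and without the cluster of low UMIs 309 genes (31.3%) were. Thinning left 434 of the 986 genes past the detection filter. It moved the median difference of the 986 from -0.24 (median SD within genotypes 0.0696) to -0.06 (0.0531), which ended the calls. On the log2 of the mean plus 1 the median was -0.21 before and after thinning. After it, 96.9% of the genes lay below 0 on that scale. Thinning keeps a gene's mean level on average, so that median could hardly move. The 986 genes were also picked as lower, so neither value on that scale tests depth. Without thinning, that scale and summed UMIs called few genes lower, so most of the 986 calls depend on the mean of logarithms. Depth or the low-UMI cluster may account for part or all of them. Thinning left fewer genes past the filter and does not settle how much. With 401 malignant-like cells of deleted hosts, depth and the low-UMI cluster cannot be told apart from the host genotype. An effect of the host on the tumor cells stays open and was not tested by itself.

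In host cells, Klrb1b and Klra8 fell in NK-like cells and Klrd1 in dendritic-like cells, and C1rb and Pianp rose in fibroblast-like cells and Cd4 and Pianp in T-like cells, and these genes lie between 9.82 and 15.4 Mb from Atg7 on chromosome 6. A candidate explanation is a segment of another mouse strain inherited with the altered Atg7 allele: of 74 calls in the 6 host classes 7 lay within 20 Mb of Atg7, where the share of tested genes gives 1.21, and of 952 calls with a set term 37 lay there against 15.9, but these counts include the genes that raised the explanation and so do not test it. With those genes except Cd4 left out, the window reached the 95th percentile of windows elsewhere in 1 of the 6 host classes (95.9 in T-like, lowest 39.8 in NK-like cells). The bound written beforehand asked for at least 4 classes in favor of a segment. It took a percentile under 95 in at least 4 classes as against a segment, and this was met. Only after the result was seen was that bound judged wrong, because the window mean covers 42 to 134 genes. A segment with few differing genes would miss it. Such a segment therefore cannot be told apart from the deletion, since all deleted libraries carry the allele; the larger share of CD4 cells for Cd4, UMIs shared among Klra paralogs, an effect of Atg7 loss on NK-like cells, and for Klrd1 in dendritic-like cells a lower share of RNA from NK-like or T-like cells, since all 8 tested cytotoxic effector genes had lower means there, also stay open. A lower depth of NK-like cells in deleted hosts is argued against, since their median was higher there by 1948 UMIs (1928 ± 543 and 3876 ± 1352, SD, n = 3 and 4, exact permutation p = 0.0857), and yet Klra8 had 0 UMIs in 463 of these cells against 62 in 322 of wild-type hosts.

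The share of T-like cells with a Cd8a or Cd8b1 UMI was lower in deleted hosts by a wide margin. With all cells at 1000 UMIs the difference was -37.5 percentage points, which argues against the depth of T-like cells. Within the barcode set that showed the smaller difference it was -36.0, so the difference did not rest on 1 set. Without the T cluster of high UMIs it was -40.4. That cluster held 17.8% ± 3.28 of T-like cells in wild-type and 11.8% ± 7.66 in deleted hosts (SD, n = 4 each). It was too small to give most of the difference, so leaving it out could not test doublets. A different makeup of the tumor T cells in hosts without Atg7 may be at work, as a hypothesis found and tested on the same data. Unequal survival of T subsets through dissociation, tumors that share an animal, and another border between T-like and NK-like clusters were not tested and stay open.

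The 8 libraries were also regrouped in every other way to see whether chance gives as many calls. Over all cells (2595 genes, highest other split 132) and in malignant-like cells (1000, highest other 109), 1 of 35 splits, the real one, gave as many. That share is the smallest possible and was read in several cell groups without adjustment, and tumors may share a mouse, so chance is not excluded. The splits used the scale of the main test, on which depth can move the differences. Chance cannot be excluded either in T-like cells (58, highest other 934, 2 of 35 splits gave as many), fibroblast-like cells (4, 607, 2 of 35) and neutrophil-like cells (8, 135, 2 of 35). The same holds for dendritic-like cells (2, 197, 3 of 35) and NK-like cells (2, 311, 4 of 35). In monocyte/macrophage-like cells the real count was 0 (highest other 3742), so all 35 splits had to give as many and nothing was tested. In each cell group the highest other split parted the barcode sets. Outside all cells and malignant-like cells it called many more genes than the real split, which points to a structure of the libraries along the sets. With a set term, the 18 splits within sets are too few for a share under 0.05; the real count and the highest other were 3879 and 0 over all cells, 2031 and 0 in malignant-like, 541 and 1 in T-like, 190 and 0 in neutrophil-like, 100 and 0 in fibroblast-like, 97 and 0 in monocyte/macrophage-like, 25 and 12 in dendritic-like and 5 and 4 in NK-like cells, and 1 of 18 splits reached the real count in each. For the number of gene lists called, chance cannot be excluded in any class: 3 of 35 splits gave as many over all cells (19, highest other 21), 4 in malignant-like (15 and 16), 4 in monocyte/macrophage-like (15 and 16), 6 in neutrophil-like (7 and 13), 12 in dendritic-like (11 and 15), 18 in fibroblast-like (6 and 12), 19 in NK-like (9 and 16) and 21 in T-like cells (7 and 18). The splits for lists ignored the barcode sets, and no version within sets was run.

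A search for a library far from the other 3 of its group found 7 in 70 groups, where chance gives about 5%. Fibroblast-like cells made up 2.28% of wild-type library 1 and 0.914% to 1.14% of the other wild-type libraries. Skeletal muscle-like cells made up 0.0363% of wild-type library 6 and 0% of the others, and 1.24% of deleted library 3 against 0% to 0.081%. Neutrophil-like cells made up 28.6% of all cells and 32.1% of immune cells in deleted library 8, against 3.62% to 6.65% and 5.16% to 8.14% in the other deleted libraries. T-like cells were 6.26% of immune cells in wild-type library 1 and 21.1% to 23.97% in the other wild-type libraries. Atg7 stood at 0.244 UMIs per 10000 in fibroblast-like cells of deleted library 4, from 9 UMIs in 72 cells, and at 0.0487 to 0.0598 in the other deleted libraries.

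Cells left out of every class comparison, though counted among all cells, also differed in share. Cluster 23, left unnamed and led by Alox15, Ccr3, F5, Retnla, Il1rl1 and Tesc, held 151 cells with a median of 640 UMIs and made up 0.0266% ± 0.0307 of cells in wild-type and 1.06% ± 1.12 in deleted hosts (SD, n = 4 each, exact permutation p = 0.0286). Deleted library 3 alone held 66.9% of these cells, and the share was 2.67% there and 0.212% to 1.00% in the other deleted libraries.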

How the results depend on the processing

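Chosen only after the results were seen were the settings with summed UMIs, with thinned cells for genes and lists, without or within single clusters, and with permutation inside the barcode sets; the other settings were fixed before the data were examined. Not run were DESeq2, edgeR without composition scaling and the edgeR test of cell numbers. Tests were kept to those for the deposited unit, a natural log, although whole UMIs were recovered and cells counted; limma on the recovered UMIs, as CPM or with median-ratio scaling, and exact permutation of shares were run instead. No paired analysis was possible because the labels give the hosts no shared replicate numbers. Where a value below changed, the cause was not tested unless stated.

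Shares of all cells kept their direction in 132 of their alternatives and turned in 3; none passed after adjustment in any, which the small number of libraries nearly fixes and which shows no stability. With 1 library left out in turn the differences in percentage points were -57.4 to -48.4 for malignant-like, 10.15 to 21.4 for fibroblast-like, 16.97 to 31.2 for monocyte/macrophage-like, 1.62 to 2.62 for dendritic-like, 1.89 to 3.75 for NK-like, 0.156 to 0.728 for endothelial-like and 0.0179 to 0.431 for skeletal muscle-like cells. They were -0.994 (without deleted library 8) to 7.32 for neutrophil-like and -0.0889 (without wild-type library 1) to 2.94 for T-like cells. At clustering resolution 0.5 the NK-like difference was -0.313 and the T-like difference 4.48, from 1.47. Shares of immune cells kept their direction in 64 and turned in 11. Left-out ranges were -2.57 to 12.7 for monocyte/macrophage-like (turned without libraries 3 and 5) and -8.09 to 0.898 for neutrophil-like cells (turned without 3, 4 and 5). They were -0.195 (without library 7) to 2.49 for dendritic-like, -9.59 to -3.44 for T-like and -0.565 (without library 7) to 3.58 for NK-like cells. At resolution 0.5 the T-like difference was 5.19 and the NK-like -9.03, and with at least 500 genes per cell the neutrophil-like was 4.45 and the NK-like -0.893. Of the T subset alternatives 26 kept their side and 7 did not. None of them changed the clustering resolution, the cell filters or the doublet handling, so they do not cover the border between T-like and NK-like cells. Permutation within barcode sets, which cannot go below 0.0556, left the differences at -37.5 (Cd8a or Cd8b1), 16.7 (Cd4) and 3.01 (Foxp3). With 1 library left out they were -39.8 to -34.4, 14.3 to 18.5 and 2.59 to 3.47. Foxp3 lost its call without wild-type library 1, 2, 5 or 6 (exact permutation p = 0.0571).

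The number of genes called over all cells, 2595, stayed within 1.5 times under 17 alternatives (1983 to 2656 with 1 library left out) and was 4327 on summed UMIs with a set term and 607 after thinning, which leaves fewer genes tested. In the classes, 66 counts stayed within 1.5 times and 95 did not. A set term gave 2031 genes in malignant-like, 100 in fibroblast-like, 97 in monocyte/macrophage-like, 190 in neutrophil-like, 25 in dendritic-like, 541 in T-like and 5 in NK-like cells. On the log2 of the mean plus 1 there were 2 in malignant-like, 2 in monocyte/macrophage-like, 24 in neutrophil-like, 1 in dendritic-like, 95 in T-like and 5 in NK-like cells, and plus 0.1 there were 39, 1, 16, 9, 109 and 6 in these and 8 in fibroblast-like cells. Summed UMIs as CPM gave 35 in malignant-like, 1 in dendritic-like, 210 in T-like and 7 in NK-like cells; with a set term they gave 117, 37, 733 and 16 there, 9 in fibroblast-like, 155 in monocyte/macrophage-like and 25 in neutrophil-like cells. Median-ratio scaling gave 50 in malignant-like, 0 in neutrophil-like, 1 in dendritic-like, 166 in T-like and 5 in NK-like cells. After thinning there were 1 in malignant-like, 1 in fibroblast-like and 0 in dendritic-like cells. Without the detection filter there were 0 in neutrophil-like, 1 in dendritic-like, 0 in T-like and 1 in NK-like cells. With at least 500 genes per cell there were 336 in malignant-like, 7 in fibroblast-like, 1 in monocyte/macrophage-like, 0 in neutrophil-like, 114 in T-like and 20 in NK-like cells. With doublets kept there were 5 in neutrophil-like, 31 in T-like and 169 in NK-like cells. Resolution 0.5 gave 0 in T-like and 13 in NK-like cells, and resolution 2 gave 377 in malignant-like and 34 in T-like cells. At most 20% mitochondrial UMIs gave 4 in dendritic-like and at least 50 cells 16 in neutrophil-like cells. Without the low-UMI cluster there were 321 in malignant-like cells, without the high-UMI cluster 90 in T-like cells, and in the cluster led by Cd8b1 alone 1.

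Leaving out 1 library gave 234 to 1181 genes in malignant-like cells (243, 234, 347 and 239 without libraries 2, 4, 6 and 8), 3 to 48 in fibroblast-like (11, 11 and 48 without 1, 7 and 8), 0 to 30 in neutrophil-like (0, 0, 3, 1, 0, 1, 16 and 30 without 1 to 8), 0 to 5 in dendritic-like (1, 0, 3, 5, 0, 0 and 0 without 2 to 8), 4 to 27 in T-like (4, 5, 9, 17, 12, 27, 23 and 27 without 1 to 8) and 0 to 4 in NK-like cells (2, 3, 0, 4, 1, 1 and 0 without 2 to 8). In monocyte/macrophage-like cells limma called 0 genes in each case and 0 with all libraries, where 223 had an unadjusted p under 0.05 and summed UMIs gave 0.

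The balance of higher against lower calls moved with the scaling. Over all cells it was 399 to 2196, and 1429 to 1677 on CPM and 1316 to 2097 with median-ratio scaling. It was 14 to 986, 7 to 28 and 19 to 31 in malignant-like cells, 3 to 1, 4 to 0 and 4 to 0 in fibroblast-like cells, and 0 to 2, 2 to 5 and 1 to 4 in NK-like cells. In neutrophil-like cells it was 5 to 3, and 6 to 1 on CPM, in dendritic-like cells 1 to 1, and 0 to 1 on both, and in T-like cells 40 to 18, and 72 to 94 with median-ratio scaling. The median log2 difference of all genes moved by over 0.1 in neutrophil-like cells, from 0.08 to -0.21 with median-ratio scaling, in T-like cells, from 0.01 to 0.13 on CPM, and in NK-like cells, from 0.06 to 0.21 on CPM.

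For gene lists, 79 counts stayed within 1.5 times and 23 did not. With an estimated correlation 0 lists passed in every class and over all cells. By fry there were 4 over all cells, 7 in malignant-like, 2 in neutrophil-like, 2 in T-like and 0 in fibroblast-like, monocyte/macrophage-like, dendritic-like and NK-like cells, against 19, 15, 7, 7, 6, 15, 11 and 9 by camera. Thinning gave 8 over all cells, 8 in malignant-like and 7 in monocyte/macrophage-like cells, the log2 of the mean plus 1 gave 3 in fibroblast-like and a set term 11 in T-like cells. With 1 library left out there were 15 to 20 over all cells, 14 to 18 in malignant-like, 4 to 9 in fibroblast-like, 12 to 16 in monocyte/macrophage-like, 6 to 10 in neutrophil-like, 10 to 14 in dendritic-like, 7 to 15 in T-like (15 without deleted library 7) and 5 to 12 in NK-like cells (5 without deleted library 4). Of the alternatives for named genes, 4665 kept direction and side, 1179 lost a call, 126 gained 1, 129 moved a value and 3 turned: G6pdx in malignant-like cells after thinning (0.0352), and Birc5 (0.0101) and Pclaf (0.00412) in the T cluster led by Cd8b1.

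Depth limits the classes unequally. Neutrophil-like cells had a median of 1001 ± 245 and 1274 ± 444 UMIs (SD, n = 4 each) and 2278 genes to test, against 9322 in malignant-like cells, and deleted library 7 held 941 cells in all.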

Other observations

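The test of the cytotoxic list within a T cluster was fixed before its result was seen but its reading was chosen after, and the comparisons of lists between classes were chosen only after the list results were seen.

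Genes of the type I interferon response, which limit virus replication, had lower means in several host classes. All 26 measured members were below 0 in dendritic-like cells and all 25 in monocyte/macrophage-like cells, at median log2 differences of -0.25 and -0.12, while in malignant-like cells 17 of 28 and in NK-like cells 13 of 19 were above 0, at medians of 0.06 and 0.02. None of them passed singly in these host classes, and 13 and 0 fell when adjusted over the list alone (camera adjusted p = 3.22e-31 and 2.34e-15, but adjusted p = 0.0843 and 0.515 with an estimated correlation). In malignant-like cells 1 of the 28 passed, Ifi27l2a, which fell, and the list had adjusted p = 0.348 with an estimated correlation. The difference between malignant-like and dendritic-like cells in the mean of this list was 0.43 (exact permutation p = 0.0571, adjusted p = 0.15 over 21 such comparisons).

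Immediate-early genes such as Fos and Egr1, which respond within minutes to growth factors and to tissue dissociation, had higher means in most host classes. Of 18 members, all 18 were above 0 in monocyte/macrophage-like and in NK-like cells and 17 in fibroblast-like and in dendritic-like cells, with medians of 0.36, 0.37, 0.30 and 0.54. None passed in these classes, and 6 rose in dendritic-like cells when adjusted over the list alone (adjusted p = 0.624, 0.704, 0.893 and 0.423 with an estimated correlation). In neutrophil-like cells 11 of 18 were above 0 and the camera direction was down, against a median of 0.05. Genes of glycolysis had lower means in several host classes, with 14 of 15 below 0 in monocyte/macrophage-like and 13 of 15 in fibroblast-like cells (medians -0.22 and -0.28; 0 and 2 fell when adjusted over the list alone; adjusted p = 0.515 and 0.619 with an estimated correlation), but in NK-like cells 11 of 15 lay above 0 (median 0.10). Core autophagy genes did not pass in any class, and their medians lay between -0.05 in malignant-like and 0.07 in NK-like cells.

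A smaller share of CD8 cells may account for the lower cytotoxic effector genes over all T-like cells, as a hypothesis that the test run here does not decide. Within the largest T cluster, led by Cd8b1, the median log2 difference of the 16 genes was 0.0527, with 7 below and 9 above 0, against -0.26 and 13 below 0 over all T-like cells. A median over members that go both ways is no evidence for it, and 3 of the genes, Nkg7, Gzmb and Ccl5, were among the 10 leading genes of the cluster. The 5 members with the lowest differences over all T-like cells still had lower means in it, untested, with Ccl5 at 109 ± 33.9 and 73.7 ± 10.1, Nkg7 at 28.4 ± 9.90 and 16.1 ± 2.11, Gzmb at 28.6 ± 12.4 and 21.01 ± 10.5, Klrd1 at 7.24 ± 1.20 and 4.21 ± 0.558 and Prf1 at 4.68 ± 2.30 and 3.17 ± 3.14 UMIs per 10000 (SD, n = 4 and 3). The smaller share and a lower level per CD8 cell therefore cannot be told apart.

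Of 21 comparisons of a list's mean difference between classes, 0 passed, and the lowest exact permutation p was 0.0286 (adjusted p = 0.1). MHC class II genes had a mean log2 difference of -0.61 in malignant-like and 0.66 in monocyte/macrophage-like cells, a difference of -1.26 between the classes at that p, and class I genes differed by 0.89 between neutrophil-like and dendritic-like cells. Cluster 21, unnamed and led by Igkc, Ighm, Siglech, Ly6d, Cd79a and Mzb1, held 93 cells with a median of 3731 UMIs and made up 0.210% ± 0.096 and 0.415% ± 0.276 of cells (SD, n = 4 each, exact permutation p = 0.286).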
